A study of Mus musculus with 8 samples.

How the data were processed

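Gene expression was measured by RNA-seq of polyadenylated RNA in 8 libraries of mouse E14 embryonic stem cells, in 4 groups of 2 libraries: control and Ssrp1 knockout cells, and control and Usp7 knockdown cells. Per the labels' protocols, total RNA was treated with DNase and the libraries were made with a VAHTS mRNA-seq V2 kit from fragmented mRNA with random primers. The deposited values are raw counts of reads per gene, in 2 tables of 4 libraries, one per experiment. Per the submitters' processing notes, the reads were handled with cutadapt, HISAT2 and featureCounts on the mouse build mm10. Their versions, the annotation release, the strand mode and the treatment of reads that map to several places are not given in the sources used here. Genes that share sequence with close copies, overlapping genes and antisense genes therefore carry counts that may belong in part to a neighbour or copy.

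Each table held 54232 genes with Ensembl identifiers and 92 spike-in sequences. All spike-in counts were 0, so the values carry no external standard and fold changes are relative to the other genes of a library. Gene symbols, coordinates, exon length and GC content came from the GENCODE annotation of GRCm38, the assembly called mm10, and 67 identifiers had no symbol there. Total counts ranged from 15879056 to 18361130 per library. Groups were taken from the sample titles and no library was left out of the reported results.

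Each experiment was tested on its own 4 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings, libraries were scaled by TMM factors, and groups were compared with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Whether a change differed between the experiments was tested in a joint fit of the 8 libraries, as the knockout change minus the knockdown change. Mean CPM values are given with the SD over 2 libraries. Overlaps of called genes were tested with a one-sided Fisher's exact test among the genes tested in both experiments.

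A total of 28 gene lists were fixed before the data were examined. They covered 2-cell-like genes, core and naive pluripotency, formative and primed pluripotency, primitive endoderm, mesoderm, neural, trophoblast and germline genes, p53 targets, histones, FACT and H2B ubiquitination, retroelement silencing, polycomb, HOX genes, the interferon and integrated stress responses, cholesterol synthesis, glycolysis, ribosome biogenesis, DNA replication and G1/S, G2/M, apoptosis, immediate early genes, imprinted genes, fibroblast markers, Y-linked genes, mitochondrially encoded genes and ribosomal proteins. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance in one direction, were run beside it. No list call held with an estimated correlation in any comparison, so each list result is given with that p. A call lost in this way does not by itself show that the genes of a list are correlated, as described below.

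The genes named were chosen by a rule fixed before the data were examined: the targets Ssrp1 and Usp7 with Supt16, and the 6 called genes with the largest change per direction that had a mean CPM of at least 5 in the higher group, complete separation of the libraries and a count of at least 10 in some library, leaving out predicted genes. For the difference between experiments 5 genes per direction were taken. Of each called list the 2 called members with the largest change were added, with 4 for 2-cell-like, naive pluripotency, primitive endoderm and p53 genes. Pou5f1, Sox2, Nanog, Cdkn1a and Mdm2 were always included, as were up to 5 shared genes per direction. Mitochondrially encoded genes were named only as list members. A gene named outside this rule is said to have been chosen after its values were seen. Where a control group held 1 to 3 counts, the ratio of normalised counts is given with an exact 95% binomial interval, which covers counting error only.

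The edgeR steps were tested on simulated data with 200 changed genes, drawn from the means, library sizes and spread of each experiment. The changed genes were taken from those with an average log2 CPM above 1. The spread followed its trend with level, and neither a GC or length trend nor a library standing apart was planted here. The rates below therefore do not cover genes with fewer counts, and the false calls may be fewer than in the real data. At a log2 change of 1, 2 and 3, the Ssrp1 simulation over 15272 genes recovered 18%, 67% and 94% of the changed genes with 7 false calls. The Usp7 simulation over 15522 genes recovered 58%, 97% and 100% with 5 false calls, and the simulation of the difference over 16546 genes recovered 14%, 55% and 86% with 7. Changes of about 2-fold are thus often missed, most of all in the difference between the experiments.

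Libraries were also checked for trends with GC content and gene length. The Ssrp1 libraries differed in both (Spearman rho with GC content -0.479 to 0.477 and with length -0.373 to 0.235), and the strongest trend with length of all 8 was that of Usp7 control replicate 1 (-0.556, and 0.271 with GC content), so fits with a per-library spline on GC content, or on GC content and exon length, were added after seeing the data. In a simulation over 15361 genes, a straight GC trend was planted in both knockout libraries, without a trend in length. Its size was chosen and not taken from the Ssrp1 libraries. Among unchanged genes the uncorrected fit made 3622 false calls and the fit corrected for GC content and length 6. These numbers do not estimate the false calls among the real ones. The other alternatives were DESeq2 size factors, upper-quartile factors, no filter beyond 1 count, a minimum mean CPM of 5, DESeq2 1.42.0, limma-voom, a joint fit of the 8 libraries, a fold threshold, the replicate number as a block, and leaving out each library in turn.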

Results

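RNA was sequenced from E14 cells, a mouse embryonic stem cell line, grown in serum with the cytokine LIF. One experiment compared cells in which Ssrp1 had been targeted with Cas9 and a guide RNA with control cells. Whether these controls are the parental line or a clone that went through editing is not stated in the labels, so a change below may hold a difference between cell lines. Ssrp1 and Supt16 together form FACT, a histone chaperone that opens and rebuilds nucleosomes during transcription and replication. The other experiment compared cells that received an shRNA against Usp7, a deubiquitinase whose known substrates include Mdm2 and p53, with control cells. The protocol for Usp7 used 1000 ng of plasmid, and 24 h later 1 ug/ml puromycin for 3 days. Each of the 4 groups had 2 libraries, with 15879056 to 18361130 counts per library. Both experiments asked how the transcriptome differs after loss of the targeted gene.

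Replicates differed from each other by far more than sampling noise, with a chi-square per gene of 43.1 in the Ssrp1 controls, 79.3 in the libraries labelled Ssrp1 knockout, 35.6 in the Usp7 controls and 11.8 in the Usp7 knockdown. No 2 libraries were therefore treated as a single one. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component, with 45.5% of the variance, separated the experiments, and the control libraries of the experiments lay on opposite sides of it. Comparisons of levels across the experiments therefore hold differences between the experiments that no test here separates from the perturbations.

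The Ssrp1 transcript (ENSMUSG00000027067, chromosome 2, 85037234 to 85047109, mm10) had 6447 and 8122 counts in the controls and 6074 and 2182 counts in the libraries labelled knockout. Its level was 441.6 ± 26.1 CPM in controls and 259.7 ± 198 CPM (SD, n = 2) in the libraries labelled knockout. Replicate 1 of these stood at 90.5% of the control mean and replicate 2 at 27.1%. The log2 change was -0.77 (SE 0.45), which did not pass the edgeR test (adjusted p = 0.41). Without knockout replicate 1 it was -1.94 (adjusted p = 0.0021), and without knockout replicate 2 it was -0.15 (adjusted p = 0.9). Editing can leave a transcript in place, so the transcript neither supports nor excludes the label of replicate 1, and directions below refer to the libraries labelled knockout. Supt16, the FACT partner (chromosome 14, 52160414 to 52197416), changed by 0.18 (SE 0.28, adjusted p = 0.79), and Usp7 by -0.07 (SE 0.28, adjusted p = 0.93); neither passed the test.

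**Figure D1:**
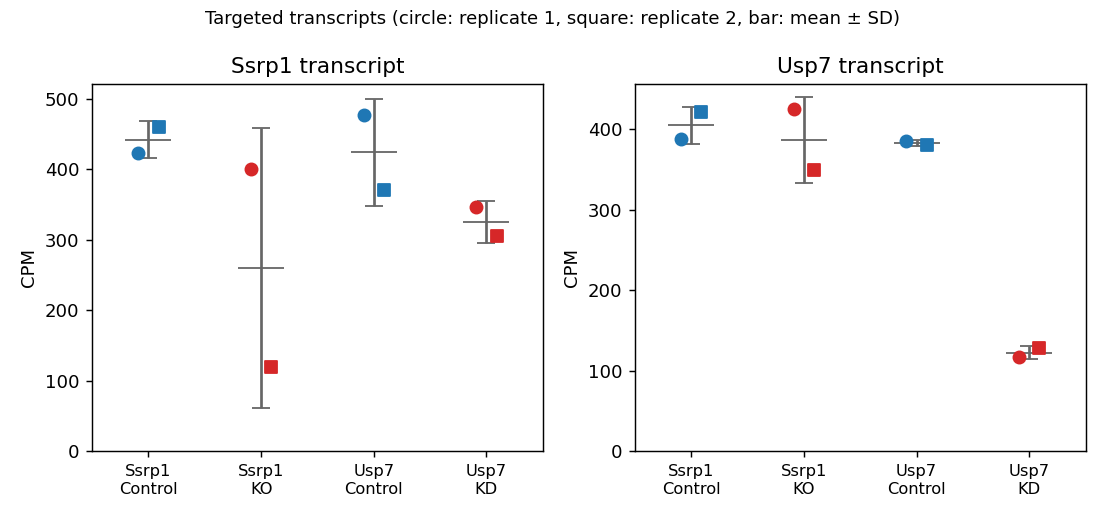
Level of the Ssrp1 and Usp7 transcripts in CPM in each of the 8 libraries, with circles for replicate 1, squares for replicate 2, and horizontal and vertical lines for the mean and SD of 2 libraries. Ssrp1 knockout replicate 1 lies at 90.5% of the control mean, while both Usp7 knockdown libraries lie below all other libraries for Usp7.

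In the libraries labelled Ssrp1 knockout, genes of the 2-cell-like state, a rare state of embryonic stem cell cultures that expresses genes of the early embryo, rose (35 of 44 tested) together with mitochondrially encoded (8 of 13) and some germline genes (7 of 32). None of these 3 list calls held with an estimated correlation (adjusted p = 0.72 each). The Nodal antagonists Lefty1 and Lefty2 and the cyclin gene Ccnd2 fell. Of 15757 genes tested, 534 were higher and 51 lower at an adjusted p under 0.05 in the edgeR test, and all 585 had a fold change over 2. After correction for GC content and length, 185 were higher and 46 lower, so the share of higher calls moved from 91.3% to 80.1%.

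Lefty1 (chromosome 1, 180935022 to 180938400) fell 22.5-fold, from 137.6 ± 37.7 to 6.169 ± 5.7 CPM (n = 2 each; log2 change -4.49, SE 0.6, adjusted p = 0.0072). Lefty2 fell 8.67-fold (log2 change -3.12, SE 0.54, adjusted p = 0.015). Ccnd2 (chromosome 6, 127125162 to 127152193), which encodes cyclin D2, fell 14-fold, from 30.36 ± 9.61 to 2.172 ± 0.278 CPM (adjusted p = 0.0055). The guidance factor gene Ntn1 fell 5.86-fold, the growth factor gene Pdgfc 5.45-fold and the noncoding Lrp8os2 10.6-fold. Among the genes that rose most were Trim43a (50.8-fold, on 8 control counts), D13Ertd608e (34.9-fold), BB287469 (23.9-fold) and Ly6a, the gene of the surface protein Sca-1 (31.4-fold, from 0.7427 ± 0.249 to 23.35 ± 5.86 CPM). Rex2, a zinc finger gene, rose 20.6-fold on counts of 47 and 86 against 2404 and 125, and its log2 change of 4.37 was 0.73 (adjusted p = 0.46) without knockout replicate 1.

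The 2-cell-like list had 44 tested members, of which 35 rose and none fell. Adjusted over the list alone, 44 rose. Its median log2 change was 3.19 and the camera adjusted p was 5.6e-38 (adjusted p = 0.72 with an estimated correlation). Gm5662, an Eif1a-like gene (chromosome 12, 88270640 to 88274500), rose 25.6-fold, from 5.638 ± 0.918 to 144.5 ± 68.4 CPM. Zfp352 rose 24.2-fold and B020004J07Rik 41.4-fold, and Gm10696 had a ratio of 55.1 (interval 9.49 to 2220) on 1 control count. The summed level of the list was 304 and 547 CPM in the controls and 1690 and 4520 CPM in the libraries labelled knockout. Many members, such as those of the Usp17l family and the Eif1a-like genes, have near-identical copies among which reads can be split, so single members are uncertain. The number of called members was 18 after the GC and length correction and 5 without control replicate 1.

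Mitochondrially encoded genes rose in the same libraries. Of 13 tested, 8 passed the test, and 12 did when adjusted over the list alone, with a median log2 change of 2.89 (camera adjusted p = 4.7e-10; adjusted p = 0.72 with an estimated correlation). mt-Nd3 rose 17.4-fold and mt-Co3 15.0-fold, the latter from 246.6 ± 27.3 to 3702 ± 2020 CPM. The share of all counts on the mitochondrial chromosome was 0.732% and 0.776% in the controls against 7.31% and 2.81% in the libraries labelled knockout. It was 2.23% and 1.67% in the Usp7 controls and 2.44% and 2.03% in the Usp7 knockdown. The Ssrp1 controls were thus the lowest of all libraries, and knockout replicate 2 lay near the Usp7 libraries. mt-Co3 has a nuclear copy, Gm28437, with nearly equal counts in each library (4098 against 4052 in control replicate 1), so the assignment of these reads is uncertain. With the GC correction, alone or with length, 1 member stayed called, 2 did without control replicate 1, and 13 were called without knockout replicate 2.

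Germline genes, which act in germ cells and meiosis, rose in part. Of 32 tested, 7 rose and none fell, and adjusted over the list alone 17 were higher and 2 lower (median log2 change 1.36, camera adjusted p = 3.7e-06; adjusted p = 0.72 with an estimated correlation). Dazl, an RNA-binding regulator of germ cells (chromosome 17, 50279395 to 50293636), rose 8.46-fold, from 6.389 ± 0.496 to 54.16 ± 1.87 CPM, but its log2 change of 3.08 was 1.6 (adjusted p = 0.067) after the GC and length correction. Tex13b rose 34.9-fold on 4 control counts and the synaptonemal complex gene Sycp2 11.5-fold on 7. After the GC and length correction 1 member stayed called. Without control replicate 1 there was also 1, without control replicate 2 there were 2, and without knockout replicates 1 and 2 there were 14 and 13.

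Primitive endoderm, trophoblast and HOX genes were higher as lists, with few single genes past the test. The filter kept 8 of the 39 HOX genes, and with low controls they can pass it mostly through the libraries labelled knockout. The same holds for low members of the other 2 lists, of which it kept 22 of 32 primitive endoderm and 18 of 30 trophoblast genes. Of 22 primitive endoderm genes 1 rose, Dab2 at 7.29-fold (9 adjusted over the list alone; median log2 change 0.99; camera adjusted p = 0.00072; adjusted p = 0.72 with an estimated correlation). Of 18 trophoblast genes 2 rose (4 adjusted over the list alone; median 0.89; camera adjusted p = 0.02; adjusted p = 0.72 with an estimated correlation). These were Igf2, which is also imprinted, with a ratio of 33.5 (interval 5.61 to 1360), and Gata3 with a ratio of 28.5 (interval 4.73 to 1170), each on 1 control count. The trophoblast call ended without knockout replicate 2 (adjusted p = 0.31). The 8 tested HOX genes were higher as a list (median 1.52, camera adjusted p = 0.033; adjusted p = 0.72 with an estimated correlation), with 0 called by edgeR, also when adjusted over the list alone, 3 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom. That call ended without control replicate 1 (adjusted p = 0.097), control replicate 2 (0.067) or knockout replicate 2 (0.29).

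Lists of growth genes and histones were lower. The histone genes were low throughout in these libraries of polyadenylated RNA. All 66 summed to 228 and 187 CPM in the controls and 108 and 84 CPM in the libraries labelled knockout. The 75 ribosomal protein genes had a median log2 change of -0.7 (camera adjusted p = 1.3e-13; adjusted p = 0.72 with an estimated correlation), with 0 called by edgeR, also when adjusted over the list alone, 31 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom. Their summed level was 190000 and 121000 CPM in the controls and 90800 and 93200 CPM in the libraries labelled knockout, so control replicate 1 stood apart, and the shortest 10% of all genes also deviated upward in that library (median log2 0.401). With the preset correlation the list call held with the GC and length correction and without control replicate 1. Of 43 histone genes, 1 fell, the linker histone gene Hist1h1c at 3.6-fold (1 adjusted over the list alone; median -0.9; camera adjusted p = 5.9e-07; adjusted p = 0.72 with an estimated correlation); without control replicate 1 its adjusted p was 0.26. The 27 glycolysis genes (median -0.34, camera adjusted p = 0.0017; adjusted p = 0.72 with an estimated correlation) and the 38 ribosome biogenesis genes (median -0.27, camera adjusted p = 0.011; adjusted p = 0.84 with an estimated correlation) were lower with 0 called by edgeR, also when adjusted over each list alone. In each of these 2 lists 7 had an unadjusted p under 0.05, DESeq2 called 3 and 1, and limma-voom 0. Of 42 genes of DNA replication and G1/S, Ccnd2 fell and Ccne2, encoding cyclin E2, rose 5.57-fold (2 higher and 1 lower adjusted over the list alone; median -0.26; camera adjusted p = 0.03; adjusted p = 0.72 with an estimated correlation). Neural genes had a median of -0.74 over 13 tested (camera adjusted p = 0.0053; adjusted p = 0.72 with an estimated correlation), with 0 called by edgeR, 3 lower when adjusted over the list alone, 3 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. The glycolysis call ended without knockout replicate 1 (adjusted p = 0.41) and the neural call without control replicate 2 (0.057). The ribosome biogenesis call ended without control replicate 1 (0.1) or knockout replicate 2 (0.57), and the G1/S call without either of these (0.18 each).

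The other 16 lists were not called. Among 34 genes of core and naive pluripotency, Rex2 rose and Nr0b1 (3.76-fold) and Tcl1 (2.41-fold) fell (2 higher and 2 lower adjusted over the list alone). The list's median was -0.07, its mean 0.07 and the camera direction lower (adjusted p = 0.38; 0.0056 without knockout replicate 1). Nr0b1 and Tcl1 had adjusted p = 0.41 and 0.38 without control replicate 1. Pou5f1, encoding Oct4, had 1355 ± 302 CPM in controls and 954.6 ± 91.4 CPM in the libraries labelled knockout (adjusted p = 0.45), and Sox2 and Nanog had log2 changes of 0.36 and 0.51 (adjusted p = 0.6 and 0.41). Of 18 formative genes, Lefty1 and Lefty2 fell, also adjusted over the list alone, and the camera adjusted p of the list was 0.053. It was 0.0038 without control replicate 1, 5.8e-08 without knockout replicate 1, 0.0088 without a filter and 0.02 with the replicate number as a block.

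Of 41 p53 target genes, Trp53inp1 (3.25-fold) and Ei24 (2.5-fold) rose, and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.33; 0.0026, with the list lower, without knockout replicate 2). The log2 change of Trp53inp1, 1.7, was 0.62 (adjusted p = 0.38) after the GC and length correction. Cdkn1a and Mdm2 had log2 changes of -0.28 (SE 0.41) and 0.31 (SE 0.32) and did not pass the test (adjusted p = 0.78 and 0.67); Cdkn1a had -1.19 (adjusted p = 0.034) without knockout replicate 2. Ei24 also lost its call with this correction. Trp53inp1 and Ei24 did not keep their call without control replicate 1, nor did Ei24 without control replicate 2.

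Camera adjusted p-values of the remaining lists were 0.079 for mesoderm, 0.086 for polycomb, 0.13 for the integrated stress response, 0.22 for retroelement silencing and for imprinted genes, 0.23 for cholesterol synthesis, 0.35 for Y-linked genes, 0.55 for G2/M and for immediate early genes, 0.6 for the interferon response, 0.66 for fibroblast markers, and 0.88 for FACT and H2B ubiquitination and for apoptosis. The camera direction was lower against a mean above 0 in the interferon (median 0.08, mean 0.13), G2/M (-0.07, 0.01), immediate early (-0.01, 0.17) and imprinted (0.04, 0.07) lists. Some of these lists were called once a library was left out: imprinted genes without control replicate 1 (adjusted p = 0.039), polycomb without control replicate 2 (0.045), fibroblast markers and immediate early genes without knockout replicate 1 (0.019 and 0.028), and Y-linked, cholesterol and retroelement silencing genes without knockout replicate 2 (0.0025, 0.0025 and 0.029). With the GC and length correction, G2/M (0.0029) and mesoderm genes (0.0036) were called.

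With 1 library left out, the spread is estimated from the pair that stays whole, so lost calls need not mean lost changes. The genes called higher had a median log2 change of 2.84, and of 2.47 to 2.99 when a library was left out. They were chosen with all libraries, so this is no independent test. The count of 585 changed genes moved with the library left out. It was 20 without control replicate 1, 358 without control replicate 2, 1512 without knockout replicate 1 and 1884 without knockout replicate 2. It was 353 with the GC correction and 231 with the GC and length correction, 205 of them among the 585, and 1497 without a filter, 1109 with DESeq2 and 1314 in the joint fit. Of the 37 called genes followed by name, 11 kept their call without control replicate 1: Lefty1, Lefty2, Ccnd2, Ly6a, Calcoco2, Dazl, Gm5662, D13Ertd608e, Usp17la, Usp17lb and mt-Co3. Without control replicate 2, 22 kept it, and those that did not were Actn3, BC002059, Ccne2, Dab2, Ei24, Gata3, Gm10696, Igf2, Lrp8os2, Pdgfc, Rex2, Sycp2, Tex13b, Tro and Zfp931. Without knockout replicate 1, Rex2, Tcl1 and Tro lost it, and with the GC and length correction 18 of the 37 kept it. The 19 that lost it with this correction were Actn3, BB287469, BC002059, Ccne2, Dab2, Dazl, Ei24, Gata3, Gm10696, Igf2, Lrp8os2, Nr0b1, Rex2, Sycp2, Tcl1, Tro, Trp53inp1, Zfp931 and mt-Nd3. The 10% of genes lowest in GC content (at most 42.4%) deviated by a median log2 of -0.613 and -0.197 in the controls and 0.636 and 0.173 in the libraries labelled knockout, and the median GC content was 42.7% for higher genes, 54.2% for lower genes and 50.3% for all tested.

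**Figure D2:**
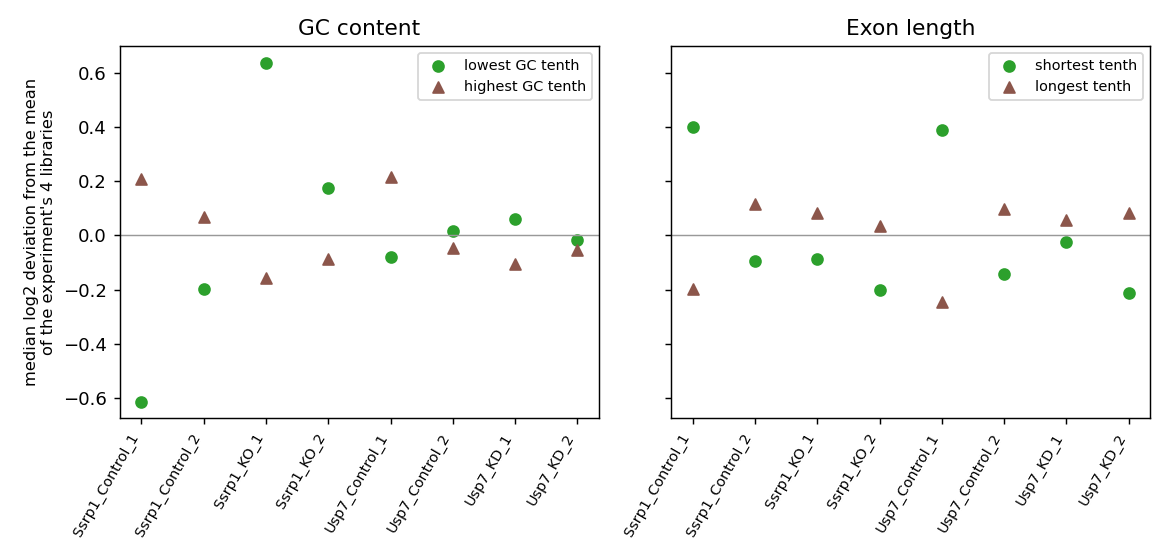
Median log2 deviation of each library from the mean of its experiment's 4 libraries, for the 10% of 10154 genes lowest and highest in GC content and shortest and longest in exon length. The genes lowest in GC lie at -0.613 in Ssrp1 control replicate 1 and at 0.636 in Ssrp1 knockout replicate 1.

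The Usp7 transcript (ENSMUSG00000022710, chromosome 16, 8689595 to 8792308, mm10) had 6546 and 6484 counts in the controls and 2106 and 2339 counts in the knockdown. It fell 3.13-fold, from 383.1 ± 3.52 to 122.6 ± 8.27 CPM (n = 2 each; log2 change -1.64, SE 0.19, edgeR adjusted p = 0.0012). Without knockdown replicate 2 the log2 change was -1.72 with adjusted p = 0.13. Ssrp1 had a log2 change of -0.38 (SE 0.21, adjusted p = 0.4) and Supt16 of 0.13 (SE 0.2, adjusted p = 0.81), and neither passed the test.

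In the Usp7 knockdown, 21 of 30 germline genes, 19 of 23 2-cell-like genes, 18 of 42 p53 target genes and 5 of 15 HOX genes rose. Of the integrated stress response 6 of 29 genes fell, and of glycolysis 2 of 27. None of these 6 list calls held with an estimated correlation (adjusted p = 0.25 for germline and p53 target genes, 0.28 for 2-cell-like, HOX and integrated stress response genes and 0.54 for glycolysis). Among the largest changes were those of the germ cell genes Taf7l (73.4-fold) and Tdrd1 (27.3-fold). The p53 targets Cdkn1a and Mdm2 rose 2.78-fold and 2.15-fold. Of 15915 genes tested, 376 were higher and 100 lower in the edgeR test, 339 and 78 of them by more than 2-fold. After the GC and length correction 475 were higher and 263 lower, so the share of higher calls moved from 79% to 64.4%.

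Germline genes rose in the knockdown. Of 30 tested, 21 rose and none fell, and adjusted over the list alone 25 were higher and 1 lower (median log2 change 2.54, camera adjusted p = 6.8e-35; adjusted p = 0.25 with an estimated correlation). Taf7l, a germ cell form of a TFIID subunit (chromosome X, 134460118 to 134476490), rose from 0.6761 ± 0.123 to 50.15 ± 14.8 CPM (log2 change 6.2, SE 0.34, adjusted p = 1.2e-05). Tex101, a germ cell surface protein gene, rose 47.9-fold, and Tdrd1, a tudor domain gene of the piRNA pathway, rose from 2.234 ± 0.493 to 61.28 ± 9.85 CPM (adjusted p = 1.2e-05). Dazl rose 20.9-fold and Sycp2 20.3-fold. Outside the list, Zfp541 (86-fold) and Mlc1 (69.2-fold), on 7 and 4 control counts, and the RNA-binding protein gene Rbm46 (29.2-fold) had the largest changes by the rule for named genes.

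Of 23 tested 2-cell-like genes 19 rose, 22 when adjusted over the list alone, and none fell (median log2 change 2.81, camera adjusted p = 4.9e-25; adjusted p = 0.28 with an estimated correlation). The filter kept 23 of the 47 list members present. With controls this low, members can pass it mostly through a high level in the knockdown. That none fell, and the median, therefore carry little weight. The level of all 47 stayed low, with a summed 12.8 and 12.5 CPM in the controls and 94.9 and 69.9 CPM in the knockdown. Their median log2 CPM was -1.79 and -1.84 in the controls and -0.15 and -0.56 in the knockdown. Usp17le had a ratio of 37.2 (interval 12.4 to 183) on 3 control counts, and Gm6763 of 31 (interval 5.18 to 1260) on 1. Usp17lb rose 14.5-fold on 5 control counts and Gm12794 11.3-fold on 4, with reads that near-identical copies can share. The number of called members was 2 without knockdown replicate 2, 7 at a mean CPM of at least 5, 6 without a filter and 5 in the joint fit.

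The p53 target list rose as well, with 18 of 42 members higher and none lower. Adjusted over the list alone, 29 were higher and 2 lower (median log2 change 0.86, camera adjusted p = 1e-17; adjusted p = 0.25 with an estimated correlation). Perp, an apoptosis gene (chromosome 10, 18845020 to 18857073), rose 4.85-fold, from 12.35 ± 0.779 to 59.9 ± 11.3 CPM. Ptpn14 rose 3.59-fold, Ano3 4.83-fold and the noncoding Trp53cor1 3.92-fold. Cdkn1a, encoding the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 60.39 ± 1.43 to 167.8 ± 13.2 CPM (log2 change 1.47, SE 0.18, adjusted p = 0.0018). Mdm2, encoding the ubiquitin ligase of p53 (chromosome 10, 117688875 to 117710758), rose from 126.5 ± 8.67 to 271.7 ± 39 CPM (adjusted p = 0.014). Without knockdown replicate 2, 1 member was called, and Cdkn1a and Mdm2 had adjusted p = 0.14 and 0.52. The number called was 12 without knockdown replicate 1, 27 without control replicate 2, 6 without a filter and 4 in the joint fit.

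Of 15 HOX genes, 5 rose and none fell, 7 when adjusted over the list alone (median log2 change 1.39, camera adjusted p = 2.9e-07; adjusted p = 0.28 with an estimated correlation). Hoxa7 rose 8.91-fold, from 0.7061 ± 0.334 to 6.344 ± 0.12 CPM, and Hoxd9 had a ratio of 13.8 (interval 4.41 to 69.3) on 3 control counts. The filter kept 15 of the 39 HOX genes, and with low controls they can pass it mostly through the knockdown. Over all 39 the median log2 CPM was -2.11 and -2.15 in the controls and -1.05 and -0.8 in the knockdown. Among 22 mesoderm genes, Wnt8a (6.62-fold) and Mesp2 (4.49-fold) rose (4 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.43 with an estimated correlation). Among 15 neural genes 3 rose, with Neurod1 4.07-fold higher and Nkx2-2 at a ratio of 19.2 (interval 4.99 to 164) on 2 control counts (5 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.43 with an estimated correlation). Krt7 rose 5.88-fold on 10 control counts among 20 trophoblast genes (10 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.58 with an estimated correlation). Hist2h3c2 rose 3.48-fold among 30 histone genes (3 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.7 with an estimated correlation). All 66 histone genes summed to only 142 and 82.4 CPM in the controls and 167 and 168 CPM in the knockdown. Low members of the mesoderm, neural and trophoblast lists can also pass the filter mostly through the knockdown. It kept 22 of 31, 15 of 30 and 20 of 30 genes present. All 30 neural genes summed to 439 and 378 CPM in the controls and 396 and 424 CPM in the knockdown. Their median log2 CPM was -1.31 and -1.38 in the controls and -0.77 and -0.37 in the knockdown. Without control replicate 2 the adjusted p was 0.078 for mesoderm, 0.079 for neural, 0.056 for trophoblast and 0.58 for histone genes. The neural call also ended without knockdown replicate 2 (0.066), and the histone call without knockdown replicate 1 (0.12) or without a filter (0.092). The number of HOX genes called was 3 and 8 without control replicates 1 and 2, and 2 and 0 without knockdown replicates 1 and 2, and 1 without a filter or in the joint fit.

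Some genes of the integrated stress response fell. Of 29 integrated stress response genes 6 fell and none rose, 12 when adjusted over the list alone (median log2 change -0.58, camera adjusted p = 2.9e-10; adjusted p = 0.28 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, fell 3.48-fold, from 25.94 ± 3.47 to 7.438 ± 2.76 CPM, and Pck2, a mitochondrial gluconeogenic enzyme gene, fell 2.56-fold. The number of called members was 10 and 15 without control replicates 1 and 2, 3 and 0 without knockdown replicates 1 and 2, 1 without a filter or in the joint fit, and 11 with the GC and length correction. Of 27 glycolysis genes, Aldoc (2.6-fold) and Vegfa (2.15-fold) fell, and 13 when adjusted over the list alone (median -0.67, camera adjusted p = 1.4e-10; adjusted p = 0.54 with an estimated correlation). Vegfa encodes an angiogenic factor and not an enzyme of glycolysis. Of 24 cholesterol synthesis genes, Dhcr7 fell 2-fold (1 adjusted over the list alone; median -0.33; camera adjusted p = 0.00019; adjusted p = 0.58 with an estimated correlation); the list call ended without control replicate 2 (adjusted p = 0.079).

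Ribosomal protein genes (75 tested, median -0.3, camera adjusted p = 2.9e-07; adjusted p = 0.76 with an estimated correlation) and ribosome biogenesis genes (38 tested, median -0.21, camera adjusted p = 0.0067; adjusted p = 0.76 with an estimated correlation) were lower as lists, with 0 genes called by edgeR, also when adjusted over each list alone. At an unadjusted p under 0.05 there were 2 and 1, and DESeq2 and limma-voom called 0. Without control replicate 1 the ribosomal protein call ended (adjusted p = 0.45) and the ribosome biogenesis list turned to higher (adjusted p = 1). This library had the strongest trend with length of all 8 (Spearman rho -0.556), with the shortest 10% of genes at a median log2 deviation of 0.39. In the list of DNA replication and G1/S, with 42 tested and a median of -0.31, 1 gene passed the test, against the list's direction: Ccnd2 rose 2-fold (1 adjusted over the list alone; camera adjusted p = 2.1e-06; adjusted p = 0.61 with an estimated correlation). Ccnd2 had a log2 change of 0.79 (adjusted p = 0.062) after the GC and length correction and of 0.74 (adjusted p = 0.84) without knockdown replicate 2.

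The largest decreases by the rule for named genes were those of the NMDA receptor gene Grin1 (3.91-fold), the DNA sensor gene Aim2 (3.82-fold, from 31.66 ± 3.12 to 8.273 ± 0.413 CPM), Chac1, the homeobox gene Vax2 (3.48-fold), Slfn9 (3.36-fold) and the noncoding Platr14 (3.29-fold). No gene of core and naive pluripotency was called by edgeR among 34 tested, also when adjusted over the list alone, with 6 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.3). Pou5f1, Sox2 and Nanog had log2 changes of -0.33, -0.33 and 0.28 with adjusted p = 0.55, 0.43 and 0.54. Camera adjusted p-values of the other lists were 0.08 for primitive endoderm, 0.11 for apoptosis, 0.13 for imprinted genes, 0.2 for the interferon response and for G2/M, 0.24 for immediate early genes, 0.38 for mitochondrially encoded genes, 0.72 for FACT and H2B ubiquitination, 0.91 for polycomb and for retroelement silencing, and 0.96 for formative genes and for fibroblast markers. Only 3 Y-linked genes were tested, too few for the list test. The camera direction differed in sign from the median or mean in the FACT (median 0.02, mean -0.06, lower), retroelement silencing (-0.04, 0.02, lower) and polycomb (-0.01, 0.04, higher) lists. Mitochondrially encoded genes were called without control replicate 1 (adjusted p = 0.00018), imprinted genes without control replicate 2 (0.015) or knockdown replicate 1 (0.0036), the interferon response without knockdown replicate 1 (0.036), and apoptosis and immediate early genes without knockdown replicate 2 (0.039 and 0.0052). With the GC and length correction G2/M genes were called (0.027).

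The count of 476 changed genes was 42 without knockdown replicate 2, 3770 without control replicate 2, 100 without a filter, 78 in the joint fit and 738 with the GC and length correction. Of the 43 called genes followed by name, 42 had a value without knockdown replicate 2 and 9 of these kept their call: Dazl, Mlc1, Perp, Rbm46, Sycp2, Taf7l, Tdrd1, Tex101 and Zfp541. Without control replicate 1, Gm12794, Gm6763, Hist2h3c2, Hoxd9, Krt7, Nkx2-2, Tex13b, Trp53cor1 and Usp17la lost it. Without knockdown replicate 1, Dhcr7, Gm12794, Hoxd9, Krt7, Tro, Trp53cor1, Usp17la and Vegfa lost it. Without a filter 20 kept it, and in the joint fit 19.

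**Figure D3:**
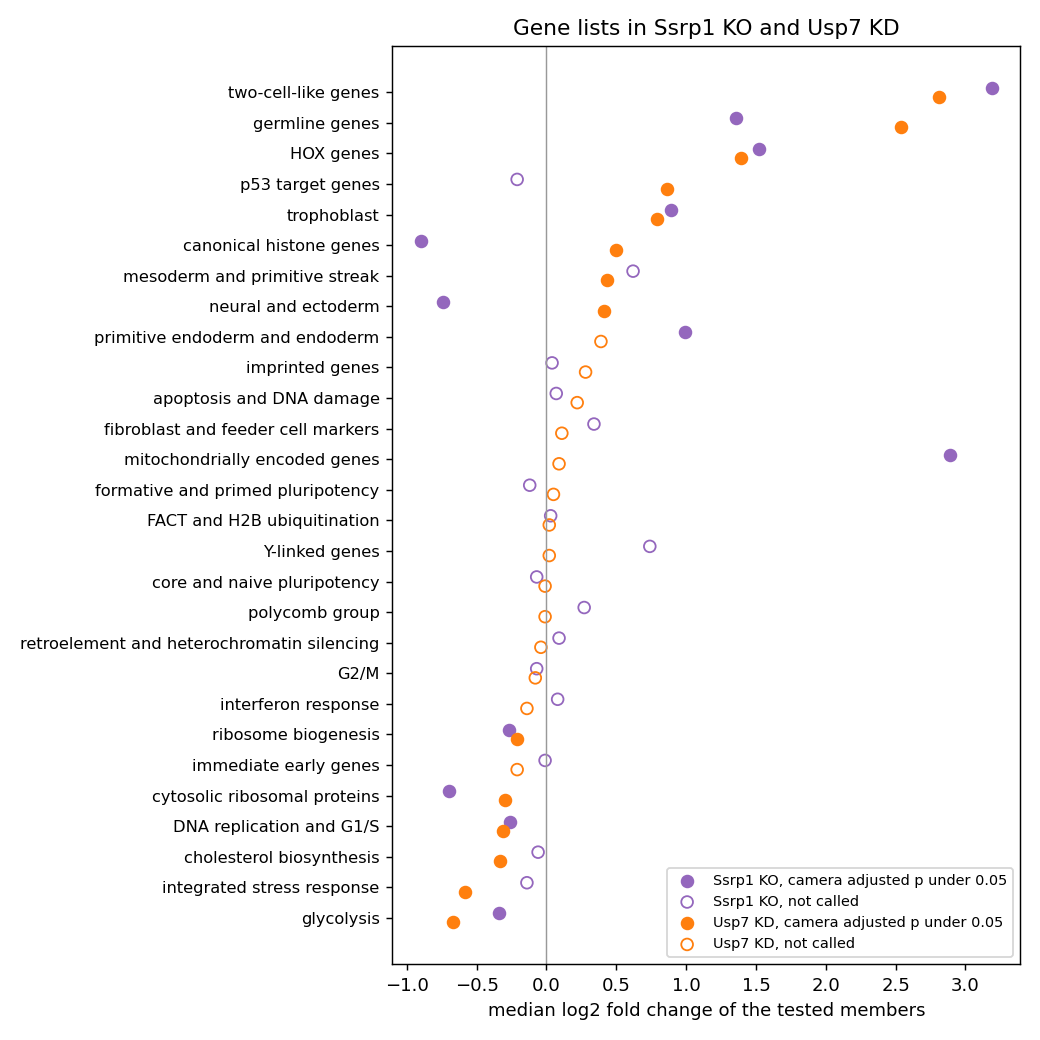
Median log2 fold change of the tested members of each of the 28 gene lists in the libraries labelled Ssrp1 knockout (KO) and the Usp7 knockdown (KD), filled where camera with the preset correlation gave an adjusted p under 0.05. The 2-cell-like list lies at 3.19 and 2.81, and Y-linked genes had too few tested members for the list test in the knockdown.

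The joint fit asked which changes differed between the experiments. Ccnd2 fell in the libraries labelled Ssrp1 knockout and rose in the Usp7 knockdown, and its difference in log2 change was -4.84 (SE 0.44, adjusted p = 0.0039). The germline gene Tdrd1 rose in the knockdown and did not pass the test in the libraries labelled knockout (0.62, adjusted p = 0.64), with a difference of -4.2 (SE 0.45, adjusted p = 0.0078), while Dazl, Sycp2 and Tex13b did not differ past the test (adjusted p = 0.085, 0.74 and 0.57). Zfp541 and Mlc1, not tested in the Ssrp1 experiment alone, differed by -7.02 and -7. Ltb4r2 differed by -4.61. In the other direction, Ly6a (4.52), the autophagy receptor gene Calcoco2 (4.1) and BC002059 (3.67) had the higher change in the libraries labelled knockout, as did the neighbouring zinc finger genes Zfp931 (4.4; chromosome 2, 178067695 to 178078476) and Zfp970 (4.13; chromosome 2, 177464733 to 177478129). Of 17052 genes, 104 had a higher and 67 a lower change in the Ssrp1 experiment, and with the GC and length correction 62 and 74, so the share moved from 60.8% to 45.6%. The difference of Ccnd2 kept its call under every setting and without any library. Its rise in the Usp7 knockdown alone did not keep its call in the joint fit, without a filter, with either correction or at the fold threshold. The call of Tdrd1 ended without Usp7 control replicate 1 or knockdown replicate 2. Calcoco2 lost its call without these or Ssrp1 control replicate 1. The other 7 of the 10 named genes lost it without Ssrp1 control replicate 1, Usp7 control replicate 1 or knockdown replicate 2, most of them also without Usp7 control replicate 2 or knockdown replicate 1, and Ly6a and BC002059 also without Ssrp1 control replicate 2. Zfp931 lost it with either correction, BC002059 with the GC correction or limma-voom, and Zfp541 with limma-voom.

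Among the lists, germline genes (8 of 32 members, 12 adjusted over the list alone, camera adjusted p = 9.4e-10; adjusted p = 0.14 with an estimated correlation) had the lower change in the Ssrp1 experiment. So had p53 targets (2 of 42, Perp and Trp73, 12 adjusted over the list alone, camera adjusted p = 2.9e-08; adjusted p = 0.68 with an estimated correlation) and histone genes (1 of 44, Hist1h1c, 3 adjusted over the list alone, camera adjusted p = 3.4e-08; adjusted p = 0.68 with an estimated correlation). Neural genes followed (2 of 17, Neurod1 and Pax6, also adjusted over the list alone, camera adjusted p = 0.0004; adjusted p = 0.19 with an estimated correlation). Without Usp7 control replicate 1 or knockdown replicate 2, 0 germline members were called, and 4 without Ssrp1 control replicate 1, Usp7 control replicate 2 or knockdown replicate 1. Trp73 and Pax6 here, and mt-Co1 among the mitochondrial genes, were named after their values were seen. Ribosomal protein genes were also lower (median -0.42, camera adjusted p = 0.00043; adjusted p = 0.95 with an estimated correlation), with 0 of 75 called by edgeR, DESeq2 or limma-voom, adjusted over the list alone, or at an unadjusted p under 0.05.

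Mitochondrially encoded genes had the higher change in the Ssrp1 experiment (2 of 13, mt-Co3 and mt-Co1, 10 adjusted over the list alone, camera adjusted p = 3.6e-07; adjusted p = 0.71 with an estimated correlation). The 2-cell-like list did too as a list (camera adjusted p = 1.5e-05; adjusted p = 0.82 with an estimated correlation), with 0 of 44 called by edgeR, also when adjusted over the list alone, 5 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The integrated stress response was higher as a list (camera adjusted p = 0.013; adjusted p = 0.64 with an estimated correlation), with 0 of 29 called by edgeR, 4 when adjusted over the list alone, 7 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Without knockout replicate 2 the 2-cell-like call ended (adjusted p = 0.23). The integrated stress response call ended without Ssrp1 control replicate 2 (0.061), knockout replicate 1 (0.13) or knockdown replicate 1 (0.073), and the ribosomal protein call without Ssrp1 control replicate 1 (0.66) or Usp7 control replicate 2 (0.4). The other 20 lists were not called, but 10 of them were under other settings. Formative genes were called with the replicate number as a block (0.044) and without Ssrp1 control replicate 1 (0.028), knockout replicate 1 (0.001), Usp7 control replicate 1 (0.047) or knockdown replicate 1 (0.05). Primitive endoderm genes were called with the GC and length correction (0.0039) and without knockout replicate 1 (0.03) or knockdown replicate 2 (0.039). Imprinted genes were called without Ssrp1 control replicate 1 (0.031), knockout replicate 1 (0.027), Usp7 control replicate 2 (0.034) or knockdown replicate 1 (0.009). Ribosome biogenesis was called without knockout replicate 1 (0.022) or Usp7 control replicate 1 (0.014), and G1/S without Ssrp1 control replicate 1 (0.049). Without knockout replicate 1, cholesterol synthesis (0.0026), glycolysis (0.024) and fibroblast markers (0.04) were called, and without knockout replicate 2 retroelement silencing (0.043) and Y-linked genes (0.0054). The number of called lists was 14 without knockout replicate 1.

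The count of 171 genes was 10 without Ssrp1 control replicate 1, 389 and 1109 without knockout replicates 1 and 2, 1 and 30 without Usp7 control replicates 1 and 2, and 18 and 1 without knockdown replicates 1 and 2; without a filter it was 945, with DESeq2 672 and with limma-voom 111.

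Of the 44 genes called higher in both experiments, 18 were on the 2-cell-like list, 7 on the germline list and 19 on neither. The lists hold only symbols fixed beforehand, so a gene on neither list can still be of either kind. Usp17lb rose 13-fold and 14.5-fold, Usp17la 13.2-fold and 8.46-fold, Sycp2 11.5-fold and 20.3-fold, Tex13b 34.9-fold and 9.57-fold, and Dazl 8.46-fold and 20.9-fold, in the libraries labelled Ssrp1 knockout and in the Usp7 knockdown. Actn3, the gene of an actinin (2.7-fold and 2.73-fold), and Tro (2.2-fold and 1.99-fold) fell in both. Both lost their call in the Ssrp1 experiment with the GC and length correction and without either control, and in the Usp7 experiment without knockdown replicate 2. Tro also lost it in the Ssrp1 experiment with limma-voom or without knockout replicate 1, and in the Usp7 experiment without knockdown replicate 1. Among 14854 genes tested in both, 44 were higher in both, where independent lists of 390 and 332 genes would share 8.7 (one-sided Fisher's exact test, odds ratio 6.26, p = 4.74e-19). There were 2 lower in both against 0.3 (one-sided Fisher's exact test, p = 0.0399), and 3 and 2 were called in opposite directions. Families that share reads are counted several times among the 44, so the p of the higher genes is too small. Across genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.187 and a Spearman rho of 0.167. The 46 shared genes became 27 with the GC and length correction, 6 without Ssrp1 control replicate 1, 30 without Ssrp1 control replicate 2, 87 and 86 without knockout replicates 1 and 2, 108 without Usp7 control replicate 2, and 8 without knockdown replicate 2.

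**Figure D4:**
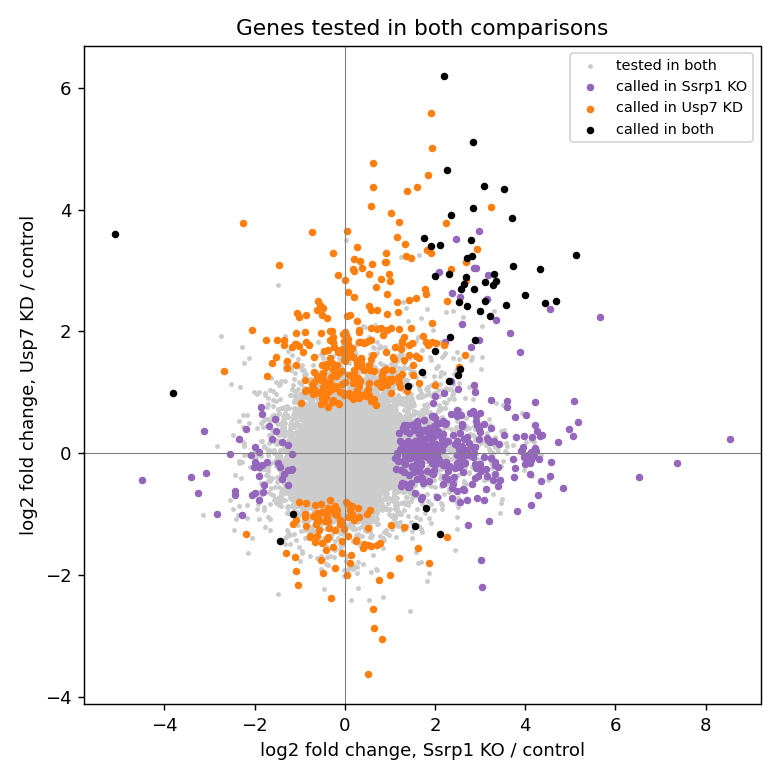
Log2 fold change of each of 14854 genes in the libraries labelled Ssrp1 knockout (KO, horizontal) against the Usp7 knockdown (KD, vertical), with genes called in either or both experiments in colour or black. The 44 genes higher in both lie in the upper right, and most called genes lie near an axis.

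**Figure D5:**
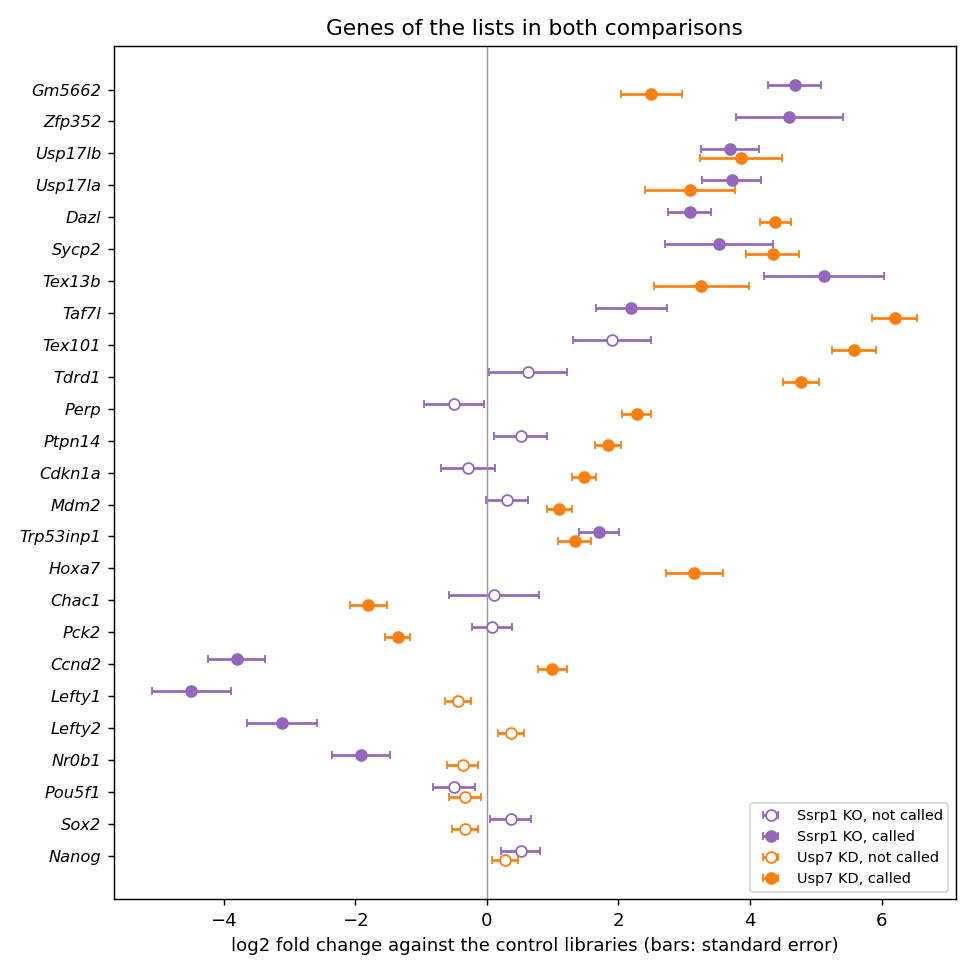
Log2 fold change of named genes in both comparisons with the standard error as horizontal bars, filled where the gene passed the edgeR test at an adjusted p under 0.05; a gene with 1 point was tested in 1 experiment. Ccnd2 lies at -3.8 in the libraries labelled Ssrp1 knockout and at 1 in the Usp7 knockdown.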

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

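The corrections for GC content and for GC content and length were chosen after seeing the data, and the other settings before the data were examined. With 1 library left in a group, that library was assumed to vary like the other groups.

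The Ssrp1 transcript stayed lower and uncalled in all settings with all libraries, with log2 changes of -0.65 to -1.01, and ranged from -1.94 to -0.15 when 1 library was left out, passing the test only without knockout replicate 1. The Usp7 transcript stayed lower and called, with -1.62 to -1.83, and ranged from -1.72 to -1.58 when a library was left out, with adjusted p = 0.13 without knockdown replicate 2. Scaling by DESeq2 size factors gave 631, 502 and 165 changed genes in the Ssrp1 experiment, the Usp7 experiment and their difference, and upper-quartile factors gave 563, 448 and 167.

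The counts of genes moved more. Without a filter there were 1497 genes in the Ssrp1 experiment, 100 in the Usp7 experiment and 945 in the difference. DESeq2 called 1109 genes in the Ssrp1 experiment and 672 in the difference, and limma-voom called 111 in the difference. The joint fit of 8 libraries gave 1314 and 78 genes in the experiments. Its spread is pooled over both experiments, with a biological coefficient of variation of 0.262 against 0.317 in the Ssrp1 and 0.181 in the Usp7 experiment alone. The cause was not tested for the other settings. The GC correction gave 353 genes in the Ssrp1 experiment. The GC and length correction gave 231 there, 738 in the Usp7 experiment and 27 shared calls. When 1 library was left out, the counts ranged from 20 to 1884 in the Ssrp1 experiment, from 42 to 3770 in the Usp7 experiment, from 1 to 1109 in the difference, and from 6 to 108 for the shared calls. In a fit of 3 libraries the spread is estimated from the pair that stays whole.

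The replicate number as a block gave 988 genes in the Ssrp1 experiment, 1471 in the Usp7 experiment, 525 in the difference and 102 shared calls. The labels do not say that replicates with the same number were handled together. Across genes, the deviations of libraries with the same number correlated with r = 0.161 over 10651 genes in the Ssrp1 experiment and 0.218 over 10689 genes in the Usp7 experiment, which with a pair of libraries per group rests on a single contrast each.

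The list calls depended on which form of the list test was run. With an estimated correlation 0 lists were called in each comparison, by camera of limma, against 12, 14 and 8 with the preset one. With fry there were 0 in the Ssrp1 experiment, 6 in the Usp7 experiment and 1 in the difference. In the Ssrp1 experiment the estimate was -0.013 for germline and -0.027 for neural genes, and in the Usp7 experiment -0.009 for neural genes. These lie below the preset 0.01, so a higher correlation does not account for the loss of these calls. For p53 target genes of the Usp7 experiment the estimate was 0.01, as preset, yet the unadjusted camera p went from 1.15e-18 to 0.0126. The 2 forms of the test thus differ in more than the correlation. For the other called lists of both experiments the estimate was above 0.01. In the Ssrp1 experiment it was highest for mitochondrially encoded (0.97), 2-cell-like (0.744) and ribosomal protein genes (0.683). In the Usp7 experiment it was highest for ribosomal protein genes (0.967). Where such estimates hold, the p with the preset correlation is too small. The cause of the lost calls was otherwise not tested. When 1 library was left out, the number of lists ranged from 11 to 15 in the Ssrp1 experiment, from 10 to 15 in the Usp7 experiment and from 7 to 14 in the difference. The ribosome biogenesis list of the Usp7 experiment ranged from an adjusted p of 1.1e-06 to 1 when a library was left out, and was higher instead of lower without control replicate 1. The cause was not tested.

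Among the single genes, lists and members followed, 3010 values under other settings were graded the same, 404 weaker, 177 stronger, 351 moved and 1 reversed. The same meant a kept direction and side of the threshold, or a count that changed only moderately. Weaker and stronger meant a call lost or gained, or a count that fell or rose by more. Moved meant an uncalled value that changed sign, or a count that went to or from none, so the 351 include changes of direction. The 1 reversed value was the called ribosome biogenesis list of the Usp7 experiment. All called genes followed by name kept their direction under all settings with a value, 37 in the Ssrp1 experiment, 43 in the Usp7 experiment and 10 in the difference. Depth limits the genes with few counts: those with 1 to 3 counts in the controls, such as Gm10696 and Gata3, have intervals over more than 10-fold. The spread between replicates is a separate limit. In simulated data 18% of genes with a log2 change of 1 were recovered in the Ssrp1 experiment against 58% in the Usp7 experiment, where replicates were closer.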

Other observations

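The test of whole chromosomes was chosen before its result was seen. The other tests by which explanations are weighed here were chosen after, though leaving out each library was planned as a setting. A test planned before, the median change without Ssrp1 control replicate 1, is given below but decides nothing. The genes named in the next paragraphs were also chosen after their values were seen.

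Single chromatin regulators passed the edgeR test in lists that were not called. In the libraries labelled Ssrp1 knockout, Rif1 rose with a log2 change of 2.04 (adjusted p = 0.028), Hells 1.99 (0.023), Atrx 1.72 (0.041) and Zfp809 1.61 (0.028), the 4 called of 37 genes of retroelement and heterochromatin silencing (4 adjusted over the list alone). The polycomb genes Suz12 (1.74) and Mtf2 (1.54) rose among 27 tested (2 adjusted over the list alone). Without Ssrp1 control replicate 1, or with the GC and length correction, 0 genes of either list were called by edgeR. Without knockout replicates 1 and 2, 5 and 4 polycomb genes were called. In the Usp7 knockdown, E2f6 rose (1.18) and Chaf1b fell (-0.84) among 37 genes of retroelement silencing, and Bmi1 rose (1.12) among 28 polycomb genes, each also adjusted over the list alone. Without control replicate 2, 11 and 7 genes of these lists were called, without knockdown replicate 1 there were 1 and 0, and without knockdown replicate 2 there were 0 of either.

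Of the immediate early list, Ccn1 and Ccn2, which encode matrix proteins and are targets of Yap, rose in both experiments. The log2 change of Ccn1 was 1.99 (SE 0.39) in the libraries labelled Ssrp1 knockout and 1.68 (SE 0.23) in the Usp7 knockdown, and that of Ccn2 was 2.31 (SE 0.38) and 1.19 (SE 0.23). Both were called adjusted over the list alone. Egr1 fell in the knockdown (-1.52, SE 0.35), where 2 of 24 were higher and 2 lower adjusted over the list alone. Without Ssrp1 control replicate 1, 0 members were called in the Ssrp1 experiment, 1 without control replicate 2, and 8 without knockout replicate 1. In the Usp7 experiment 7 were called without control replicate 2 and 1 without knockdown replicate 2.

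Calls in the Ssrp1 experiment leaned to higher and AT-rich genes, with a median GC content of 42.7% against 50.3% of tested genes. Of the 585 calls, 35% held after the GC and length correction, so library trends in GC content and length are a candidate explanation for part of them. In the 380 genes that lost their call the median absolute log2 change went from 2.29 to 1.36 and the median SE from 0.47 to 0.39, while in the 205 kept it went from 3.17 to 3. Whether Ssrp1 control replicate 1 is the source of the lean stays open: without it calls fell from 585 to 20, and over all 10154 genes 74.3% of the gap of the lowest-GC genes between knockout and control stayed, with 103% for knockout replicate 1 and 45.7% for replicate 2. The median log2 change of the genes called higher, planned as the test before (2.53 without it against 2.84), decides nothing, since these genes were called with that library. For the 2-cell-like genes both explanations are argued against as the whole cause, with medians of 2.66 after the correction and 2.69 without that library against 3.19, and 44 of 44 members above 0, although fewer members were called (18 and 5 of 44 against 35); an effect of the Ssrp1 knockout stays open and untested.

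The Ssrp1 transcript stood at 90.5% of the control mean in knockout replicate 1. In this library the 44 2-cell-like genes lay a median log2 of 1.75 above the higher control, with 44 of 44 above it. In knockout replicate 2 they lay 3.06 above it. This argues against a library like the 2 Ssrp1 controls carrying the knockout label. Control cultures can differ in this list, with a summed 304 and 547 CPM in the Ssrp1 controls against 12.8 and 12.5 CPM in the Usp7 controls. Its members also move together (estimated correlation 0.744), so they are not 44 separate observations. That a control culture with a higher level of these genes gave knockout replicate 1 therefore stays open. In this library Y-linked genes summed to 156 CPM, against 33.4 to 62.4 in the other Ssrp1 libraries and 118 to 138 in the Usp7 libraries, and Rex2 had 2404 counts against 47 to 125 and 987 to 1441, but on the first principal component it lay with the Ssrp1 libraries (-32.9, against -60.8 to -40.6 and 27.6 to 64.6). A library from outside these groups, a mixed culture or an edit that leaves the transcript stable stays open, and no value here decides among them. The sequence at the edited site was not analysed here.

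Of the 534 genes higher in the libraries labelled Ssrp1 knockout, 88 (16.5%) were at least 4-fold (a log2 gap of 2) lower in the Ssrp1 controls than in the Usp7 controls, a gap chosen after seeing the data; call and gap use the same 2 Ssrp1 controls, so part of these arise without any cause, but with the call made without control replicate 2 and the gap taken from it alone, 28 of 300 (9.33%) had it against 1.39% of tested genes, and 3 of 16 against 3.01% for replicate 1. Their median log2 CPM was 0.41 in Ssrp1 controls, 3.44 in the libraries labelled knockout, 3.59 in Usp7 controls and 3.63 in the knockdown, and 20 are zinc finger genes by name, such as Zfp931 and Zfp970, with 21 near the distal end of chromosome 2. Gain or loss of a whole chromosome is argued against, since 0% lay on chromosomes with a corrected median log2 change of at least 0.4, while GC and length trends stay open: 94.3% kept a log2 change of at least 1 after correction over 8 libraries (median 3.3 before and 2.15 after), an easy bar for genes chosen by their gap, but 62 of 88 kept their call there and 20 in the Ssrp1 libraries alone, where the 68 others went from 3.24 (median SE 0.7) to 2.07 (0.57). A local difference between cell lines, such as a deletion or a silenced cluster in the Ssrp1 control line, may account for part, since 42 of 82, with 6 mitochondrial genes and nuclear copies that share reads left out, had another of them within 1 Mb against a mean of 10.4 and a highest of 27 in 10000 random draws. Zinc finger genes lie in clusters and can share reads, so a shared regulator of such clusters that responds to loss of Ssrp1 would give the same value and stays open, as does a difference in the control cells, whose origin is not stated.

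The summed level of the 2-cell-like list differed between the controls of the experiments, with 304 and 547 CPM in the Ssrp1 controls and 12.8 and 12.5 CPM in the Usp7 controls. Germline genes summed to 703 and 489 CPM in the Ssrp1 controls, 799 and 789 in the libraries labelled knockout, 485 and 446 in the Usp7 controls and 1470 and 1780 in the knockdown.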
